A study of Glaesserella parasuis SH0165 with 9 samples.

How the data were processed

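RNA of Glaesserella parasuis (also called Haemophilus parasuis) strain SH0165 was measured on 9 one-colour Agilent arrays of a custom design, 1 array per culture sample, with cRNA labelled with Cy3 per the labels. The 9 arrays formed 3 groups of 3, assigned from the sample labels: an untreated control, 0.25 µg/ml tilmicosin and 8 µg/ml tilmicosin. Per the labels and the design text, the arrays of a group came from separate experiments.

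The scanner files held spot intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity had been background-subtracted and corrected for trends across the array, per the file headers. No header named a scaling between arrays. The raw median intensity of each spot and of its local background, deposited in the same files, was used for the negative control spots and for a normexp background correction with an offset of 50. Flags for spots well above background, saturated spots and outlier spots were also those deposited by the authors. A table of the authors' processed values was deposited on a log2 scale: its columns had medians of 12.72 and nearly equal upper quartiles, and they correlated with the log2 scanner values of the matching arrays at r between 0.995 and 0.9996. How that table was scaled is not given in the sources used here, so it served as an alternative setting.

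Each array's file listed 15536 spots, of which 15000 were non-control spots of 2052 probes. Of these probes, 1380 had 6 spots each and 672 had 10. The files and the tables given with them do not pair the probe IDs with genes: 0 probes had a gene name. The 22 gene lists and the panel of efflux and ribosomal protein genes fixed before the data were examined were therefore not tested, and results refer to probes rather than genes.

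In the main setting, the log2 processed intensity of each spot was reduced by the array's 75th percentile over non-control spots. Spots marked as outliers were left out (253 to 402 per array), and at least 4 spots of each probe remained on each array, which were averaged. A probe counted as above background on an array when a share of at least 0.5 of its spots was well above background. Testing covered the 2036 probes above background on all 3 arrays of at least 1 group, 1994 of which were above background on all 9 arrays. No array had a saturated spot (0 of the non-control spots). The 9 arrays were fitted together with limma 3.58.1 (lmFit and eBayes, group as the term) in R 4.3.3 with the data.table package (version 1.17.8), and 3 contrasts were taken, all two-sided. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast, and the count with a fold of at least 2 was taken beside it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

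Named probes followed a rule fixed before the data were examined: the largest rises and falls among called probes whose 3 arrays of one group all lay on one side of the 3 arrays of the other. The rule's demand for an annotated gene could not be applied, and its number was reduced to 2 rises and 2 falls per comparison because the probes have no gene names.

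The procedure was tested on simulated data for the 2036 probes, with 200 probes changed in each contrast. In the simulation of 0.25 µg/ml against control, 54% of 1.1-fold, 98% of 1.25-fold and 100% of 1.5-fold and 2-fold changes were recovered, and 2.22% of calls were false. In that of 8 µg/ml against control the recovered shares were 66% at 1.1-fold and 100% at each larger size, with 3.17% false calls. In that of 8 against 0.25 µg/ml they were 54% at 1.1-fold and 100% at each larger size, with 5.85% false calls. The noise was drawn independently for each probe at the fitted within-group spread, without a slide difference. These shares therefore do not give the rate of false calls in the real comparisons. Of 15 spike-in probes, whose RNA is added equally, 6 at 0.25 µg/ml and 5 at 8 µg/ml were called against control.

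The correlation between the fold changes of the 2 treatments was set against 100 simulations of unchanged groups compared with the same controls, since both contrasts share the control arrays. Within groups, array pairs correlated across probes at r between 0.9992 and 0.9998, and between groups at r between 0.986 and 0.991. The squared difference of within-group pairs was 1.78 to 7.57 times that allowed by the spread of spots within an array, so each array was counted as 1 sample; repeat labellings of 1 RNA would exceed that spread too and are not excluded by it. Deviations of same-numbered control and 8 µg/ml arrays from their group means correlated at 0.123 to 0.199 in the 3 pairs, and those of other pairs of these groups at -0.192 to 0.057. Deviations from a mean of 3 arrays are not independent, and differently numbered control and 0.25 µg/ml arrays reached 0.392. A pairing by number was therefore not established, the labels state none, and a replicate block served as an alternative only. The median within-group SD was 0.05 on the log2 scale. With 3 arrays per group, the number of arrays limits the precision of each value.

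The 3 control arrays lay on slide 1 and were read in scan 1, and the 6 treated arrays lay on slide 2 and were read in scan 2. Treatment and slide therefore cannot be told apart in the comparisons with control, and a slide term could not be fitted for them. The 8 and 0.25 µg/ml arrays shared a slide but lay in different columns of it. Alternatives covered the background correction, the scaling between arrays, the filter on dim probes, the handling of spots, the variance model, the arrays entering the fit, a replicate term and leaving out each array in turn.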

Results

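RNA levels were compared between cultures of Glaesserella parasuis SH0165 grown with and without tilmicosin. G. parasuis is a bacterium of the pig airway that causes Glässer's disease, and tilmicosin is a veterinary macrolide, an antibiotic class that binds the large ribosomal subunit and blocks the growing peptide. The question addressed was which transcripts differ when the bacterium meets the drug at a low dose for a long time or at a high dose for a short time. Control cultures were grown for 12 h without drug. Low-dose cultures were grown for 16 h with 0.25 µg/ml, and high-dose cultures received 8 µg/ml for 50 min with a stated time of 12 h, which the labels do not say includes the exposure or not. Dose, exposure and culture time thus differed together, and each comparison is one of whole treatments. Each group had 3 arrays. The median processed intensity of the non-control spots was 6885 to 9384 on the control arrays, 6905 to 7282 at 0.25 µg/ml and 6162 to 6842 at 8 µg/ml. Of 2052 probes, 2036 to 2041 were above background on each control array, 2017 to 2033 on each array at 0.25 µg/ml and 1998 to 2003 on each array at 8 µg/ml. Levels are given on the log2 scale relative to the 75th percentile of each array, and probes are identified by the IDs in the files, which do not pair them with genes.

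After 16 h with 0.25 µg/ml tilmicosin, transcripts of 950 probes rose and those of 661 fell against control, out of 2036 tested (limma, adjusted p under 0.05). Most of these changes were small: the median called rise was 1.29-fold and the median called fall 1.22-fold. A change of at least 1.5-fold was seen for 219 rising and 112 falling probes, and one of at least 2-fold for 33 rising and 22 falling probes. The largest rise was that of CUST_1801_PI425463947, from -5.02 ± 0.07 (SD, n = 3) in control to -2.85 ± 0.05 (SD, n = 3), a log2 fold change of 2.17 ± 0.05 (SE) or 4.50-fold (limma, adjusted p = 2.08e-10). CUST_1800_PI425463947 followed, from -3.22 ± 0.02 to -1.36 ± 0.02 (SD, n = 3), a rise of 3.63-fold (limma, adjusted p = 1.43e-11). The largest fall was that of CUST_211_PI425463947, which dropped 4.52-fold from -5.40 ± 0.04 to -7.58 ± 0.07 (SD, n = 3; limma, adjusted p = 5.55e-11). This dim probe's log2 fold change was -2.18 in the main setting and -1.58 with a normexp background correction, under which CUST_598_PI425463947 fell further, at -1.69. CUST_598_PI425463947 fell 3.50-fold, from -3.01 ± 0.02 to -4.82 ± 0.05 (SD, n = 3; limma, adjusted p = 1.57e-10).

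The called probes made up 79.1% of those tested, and 1556 of the 1611 changed less than 2-fold. For 1687 probes (82.9%) all 3 treated arrays lay on one side of all 3 control arrays, where chance gives 10%. The larger number of rises did not hold with the authors' processed values (754 rose, 805 fell) or quantile normalization (803 and 834). Both settings give the arrays equal or nearly equal medians, which favours an even split by construction. More rises than falls were called with median scaling (834 and 776), spike-in scaling (833 and 417) and normexp (964 and 619). The balance thus depends on the scaling. In the main setting the larger number of rises was most marked among dim probes. Of the 408 dimmest tested probes 215 rose and 99 fell, and of the next 407 these were 216 and 126. The brighter sets of 407 had, from dim to bright, 178 and 151, 161 and 152, and 180 and 133. Every control array lay on 1 slide and every treated array on another, so this comparison cannot be told apart from one between slides.

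After 50 min with 8 µg/ml tilmicosin, transcripts of 764 probes rose and those of 594 fell against control (limma, adjusted p under 0.05). The median called rise was 1.19-fold and the median called fall 1.22-fold. At least 1.5-fold changes were seen for 112 rising and 92 falling probes, and at least 2-fold changes for 28 rising and 26 falling probes. The probes with the largest rises were the same as at the low dose. CUST_1801_PI425463947 reached -2.23 ± 0.10 (SD, n = 3), 6.90-fold above control (limma, adjusted p = 3.33e-11). CUST_1800_PI425463947 reached -1.09 ± 0.02 (SD, n = 3), 4.38-fold above control (limma, adjusted p = 3.66e-12). The largest falls were those of CUST_1016_PI425463947 and CUST_1924_PI425463947. CUST_1016_PI425463947 dropped 5.05-fold, from 1.04 ± 0.04 to -1.30 ± 0.02 (SD, n = 3; limma, adjusted p = 3.85e-12). CUST_1924_PI425463947 dropped 4.98-fold, from -1.71 ± 0.05 to -4.02 ± 0.03 (SD, n = 3; limma, adjusted p = 3.89e-12). Both also fell at 0.25 µg/ml, by 1.87-fold and 2.35-fold.

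The called probes were 66.7% of those tested, and 1304 of the 1358 changed less than 2-fold. The 3 arrays at 8 µg/ml lay on one side of the 3 control arrays for 1383 probes (67.9%), against 10% by chance. At 8 µg/ml 30 of the tested probes were above background on no array; 13 of these were called against control, 0 of them at 2-fold or more. The larger number of rises did not hold with quantile normalization (685 rose, 724 fell), median scaling (656 and 678) or the authors' values (626 and 711). These settings give the arrays equal or nearly equal medians, which favours an even split by construction. More rises than falls were called with spike-in scaling (568 and 379) and normexp (839 and 531), so the balance depends on the scaling. This comparison, too, was one between slides.

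**Figure D1:**
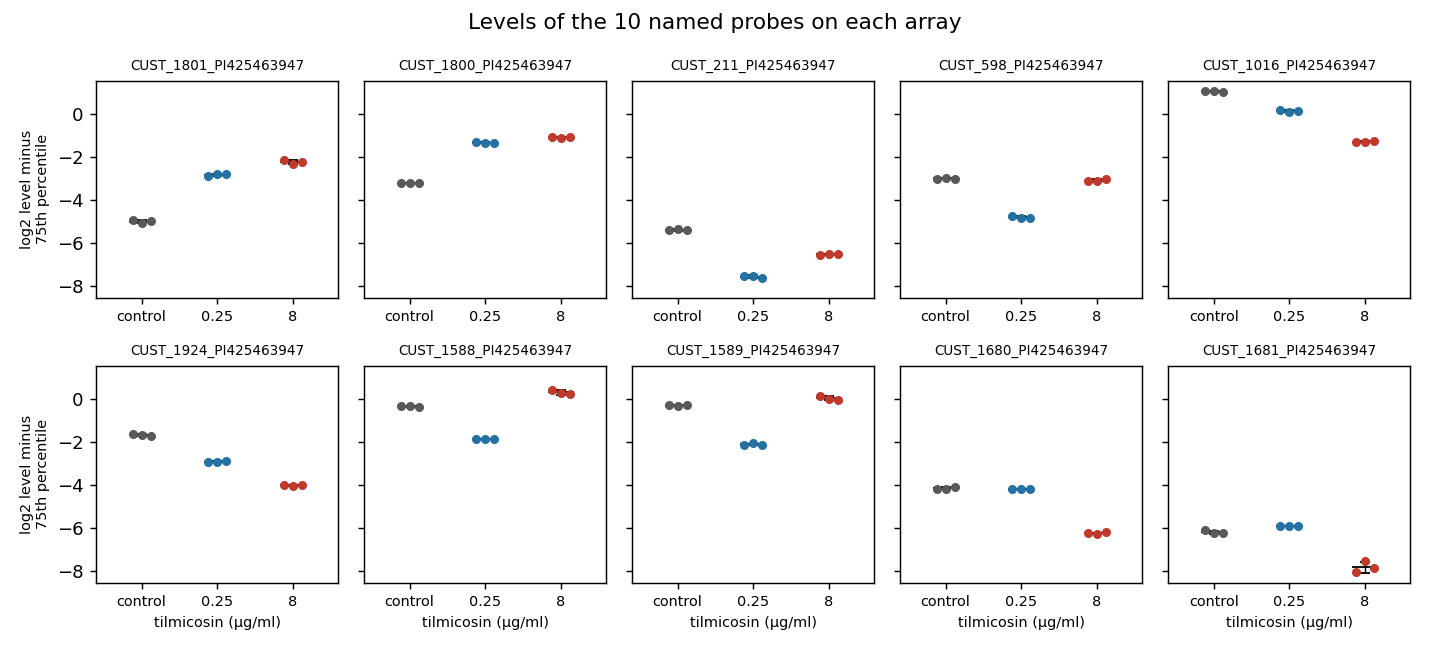
Log2 level minus the array's 75th percentile (vertical axis) of the 10 named probes in control cultures and at 0.25 and 8 µg/ml tilmicosin (horizontal axis). Points are the 3 arrays of a group and bars the mean ± SD; CUST_1801_PI425463947 rose from -5.02 in control to -2.85 and -2.23, and CUST_1680_PI425463947 was at -4.17, -4.20 and -6.25.

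The treatments shared part of their changes. Transcripts of 594 probes rose in both treatments and those of 357 fell in both, while 188 were called in opposite directions: 133 rose at 0.25 µg/ml and fell at 8 µg/ml, and 55 did the reverse. Median log2 changes at 0.25 and 8 µg/ml were 0.28 and -0.26 for the 133, and -0.16 and 0.14 for the 55. Spike-in probes changed by up to 0.19 and 0.33 against control, so a slide difference stays open for some of these directions. Among the 90 probes that changed at least 2-fold in either treatment, 15 rose and 4 fell at least 2-fold in both, and 0 changed 2-fold in opposite directions. Across the 2036 probes, which are not independent replicates, the log2 fold changes of the treatments correlated at r = 0.619. Treated groups and controls simulated without any change gave a mean r of 0.498 (0.407 to 0.588 over 100 simulations). Such a value follows by construction when 2 contrasts of pure noise share their controls, whatever the size of the noise. It therefore does not tell what part of the observed r comes from the shared controls. The covariance of the fold changes was 0.101 against a simulated mean of 0.00111. Lists of the same sizes drawn independently would share 356.5 rises and 192.8 falls, and the simulation of unchanged groups, which by construction has almost no calls to share, gave means of 0 rises and 0.01 falls. The simulated covariance was at most 0.00153, which argues against sampling noise of the shared controls as more than a small part of the observed covariance. The 3 control arrays cannot be split into 2 sets of at least 2 to remove that noise. A deviation common to all 3 control arrays was not simulated and stays open. Both treated groups also lay on the same slide, apart from the controls.

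**Figure D2:**
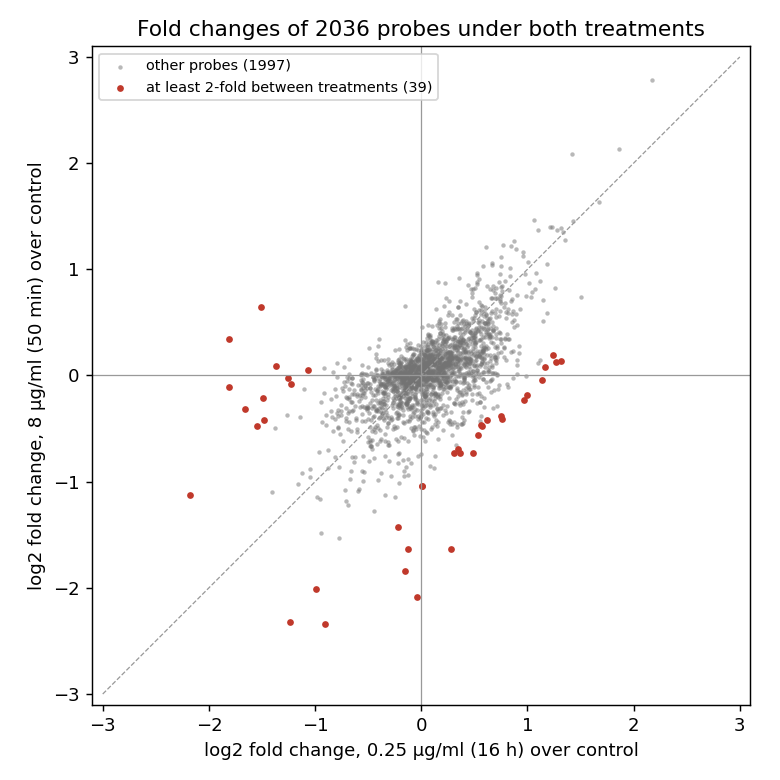
Log2 fold change of each of 2036 probes at 8 µg/ml tilmicosin for 50 min over control (vertical axis) against that at 0.25 µg/ml for 16 h over control (horizontal axis), each from 3 arrays per group. The dashed line marks equal change; the 39 probes in red differed at least 2-fold between the treatments, and the correlation over all probes was r = 0.619.

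The direct comparison of 8 with 0.25 µg/ml asked which transcripts respond differently to the treatments, and both groups lay on the same slide. Levels of 657 probes were higher and those of 817 lower at 8 µg/ml (limma, adjusted p under 0.05). This balance turned with quantile normalization (792 higher, 706 lower) and the authors' values (748 and 690). Both settings give the arrays equal or nearly equal medians, which favours an even split by construction. Spike-in scaling kept more lower probes (426 higher, 587 lower). Among the 408 dimmest tested probes 78 were called higher and 200 lower at 8 µg/ml, and among the next 407 these were 116 and 196. The middle 407 had 146 and 163. The 407 brightest had 155 higher and 123 lower, and the 407 below them 162 and 135. With a normexp background correction the whole balance was 700 higher and 715 lower. The cause of this dependence on level was not tested. At least 2-fold differences were found for 12 higher and 27 lower probes, and at least 1.5-fold differences for 51 and 134. Against control, which lay on another slide, CUST_1588_PI425463947 and CUST_1589_PI425463947 fell at the low dose and rose at the high dose. The rise of CUST_1589_PI425463947 at 8 µg/ml was 0.34 on the log2 scale. A spike-in probe, whose RNA is added equally, reached 0.33 there, so a slide difference stays open for the direction of that rise. CUST_1588_PI425463947 was 2.86-fold below control at 0.25 µg/ml and 1.57-fold above it at 8 µg/ml, a 4.48-fold difference from -1.88 ± 0.02 to 0.28 ± 0.11 (SD, n = 3; limma, adjusted p = 1.93e-10). CUST_1589_PI425463947 was 3.50-fold below control at 0.25 µg/ml and 1.27-fold above it at 8 µg/ml, a 4.44-fold difference from -2.13 ± 0.04 to 0.02 ± 0.08 (SD, n = 3; limma, adjusted p = 1.44e-10). CUST_1680_PI425463947 was 4.13-fold lower at 8 than at 0.25 µg/ml, at -6.25 ± 0.03 against -4.20 ± 0.02 (SD, n = 3; limma, adjusted p = 2.05e-11), with a log2 fold change of -0.04 ± 0.03 (SE) between 0.25 µg/ml and control (limma, adjusted p = 0.277). CUST_1681_PI425463947 was 3.76-fold lower at 8 µg/ml, at -7.84 ± 0.25 against -5.93 ± 0.01 (SD, n = 3; limma, adjusted p = 4.94e-08). This probe was above background on 8 of the 9 arrays, and its log2 difference of -1.91 became -1.11 with a normexp background correction.

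Some probes passed 2-fold in 1 treatment and not in the other. Picking them this way builds in much of a difference between the treatments, and 72.4% of all tested probes were called in the direct test. Their change in the other treatment reached a log2 size of 0.96 at 8 µg/ml and 0.99 at 0.25 µg/ml, close to 2-fold. At 0.25 µg/ml 36 probes changed at least 2-fold that did not at 8 µg/ml, and 34 of them differed between the treatments in the direct test. Of these, 16 differed by 2-fold or more, 5 having risen and 11 having fallen at 0.25 µg/ml. At 8 µg/ml 35 probes changed at least 2-fold that did not at 0.25 µg/ml, and all 35 differed in the direct test. Those that differed by 2-fold or more were 9, all of which had fallen at 8 µg/ml. The median size of change against control was 0.25 on the log2 scale at 0.25 µg/ml and 0.17 at 8 µg/ml, and 1259 probes (61.8%) had the larger size at 0.25 µg/ml. For 1567 probes (77.0%) the arrays of the 2 treatments did not overlap, against 10% by chance. The arrays at 8 µg/ml lay in the second column of the slide and those at 0.25 µg/ml in the first, so the treatments cannot be told apart from the columns.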

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

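The tests of the negative control spots in this part were all chosen only after their brightness was seen, and those by array row and local background replaced tests whose results had been seen. These 77 spots per array carry a sequence meant to bind no transcript and enter no comparison above. Their raw median signal was higher on the arrays at 8 µg/ml, with a group mean of 57.8 ± 9.29 (SD, n = 3), than on the control arrays at 41.8 ± 2.36 (SD, n = 3). At 0.25 µg/ml it was 45.0 ± 1.73 (SD, n = 3). The arrays at 8 µg/ml ranged from 51.5 to 68.5 and the control arrays from 40 to 44.5 (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 arrays can give).

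Among the 15 spots in the lowest array rows the group mean of the median signal rose by 39.8 between control and 8 µg/ml, and among the 15 in the highest rows by 2.00, a ratio of 0.0502, which argues against binding of labelled RNA spread evenly over the array. Spearman's rho of the spot signal with the array row lay between -0.639 and -0.509 on the arrays at 8 µg/ml, between 0.33 and 0.49 at 0.25 µg/ml and between -0.009 and 0.207 on the control arrays. The local background around these spots did not share this gradient at 8 µg/ml, where its rho lay between -0.0392 and 0.298, and its group mean was 50.3 ± 4.04 against 54.8 ± 2.57 in control (SD, n = 3), which argues against an uneven background of the array surface. Signal bound unevenly at the spots themselves stays open, and position on the slide cannot be told apart from treatment, because only 1 group had arrays in the second slide column. Slide and scan cannot be told apart from treatment either, because the control arrays lay on another slide read in another scan. A biological difference between the cultures was not tested.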

How the results depend on the processing

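The normexp correction on median signals, the median of spots, the keeping of outlier spots, the restriction to the 1628 brightest probes and the replicate block in 2 groups alone were chosen only after the data were seen. Counts of called probes stayed within 1.5 times the main count under every alternative run except the demand for a 2-fold change, which by construction left 55 probes at 0.25 µg/ml, 54 at 8 µg/ml and 39 between the treatments. Spike-in scaling called 1250, 947 and 1013 probes. Leaving out each array in turn gave 1525 to 1650, 1258 to 1347 and 1354 to 1503 probes. The correlation of the treatments' fold changes was 0.632 with normexp, 0.592 with the authors' values and 0.633 over the 1628 brightest probes, moves of at least 1 SD (0.0127 over 27 sets of 1 array per group, which ranged from 0.589 to 0.636), and the cause was not tested. Without single arrays it ranged from 0.609 to 0.624. For the 12 named changes, all 264 values under the alternatives and with arrays left out kept their direction and their call, the highest adjusted p being 2.82e-06 (limma). The restriction to the 1628 brightest probes removed CUST_211_PI425463947, CUST_1680_PI425463947 and CUST_1681_PI425463947. That to probes above background on all 9 arrays removed CUST_1681_PI425463947. The 264 values hold none for these probes in those settings. Fitting the 2 treated groups alone, on their shared slide, called 1484 probes. A replicate block called 1605, 1345 and 1470 probes, and 1352 in a fit of the control and 8 µg/ml arrays alone, so it moved no count by over 1.5 times and ended no named call. In the other 2 comparisons the deviations of same-numbered arrays correlated at -0.246 to 0.0411 (0.25 µg/ml and control) and -0.0528 to 0.123 (both treatments), and 4 of 9 arrays correlated best with their own number. Not run were normexp on mean signals, which the files used here do not hold, rules on several probes of a gene and gene list tests, which need gene names, and a slide term, which the design cannot fit. Background limits the dimmest probes; normexp lowered the size of all 12 named changes, most for 2 dim probes.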

Other observations

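The tests of spike-in RNA, of strongly changed probes between treatments, of the spread between arrays, of neighbouring probe numbers, of the share of array noise and of runs were chosen only after related results were seen. Probes with consecutive numbers in the design changed together. Runs of at least 3 consecutive probes that were all called in 1 direction with changes of at least 1.5-fold numbered 24 at 0.25 µg/ml (18 up, 6 down), against a mean of 2.51 and at most 9 when the numbers were shuffled. At 8 µg/ml there were 13 such runs (7 up, 6 down), against a mean of 0.473 and at most 5. Between the treatments there were 18 (3 higher and 15 lower at 8 µg/ml), against a mean of 0.545 and at most 5. Each permutation p was 1e-04, the smallest that 10000 shuffles can give, and 1e-04 after adjustment over the 3 comparisons.

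The longest run at 8 µg/ml held 7 probes that rose by 1.51-fold to 6.90-fold, and all 7 were also called higher at 0.25 µg/ml, by 1.20-fold to 4.50-fold. A run of 3 probes fell by 2.01-fold to 4.23-fold at 8 µg/ml and another of 3 by 2.06-fold to 3.58-fold, and all members of both were lower at 8 than at 0.25 µg/ml in the direct test. At 0.25 µg/ml a run of 4 probes fell by 1.78-fold to 2.39-fold and one of 3 fell by 2.33-fold to 3.16-fold. In the first of these, 0 of 4 probes were called at 8 µg/ml, and all 4 differed between the treatments. The longest run between the treatments held 8 probes that were 1.55-fold to 2.30-fold lower at 8 µg/ml. These runs were picked after their values were seen.

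A hypothesis for these runs is that probe numbers follow the order of genes and that neighbours are transcribed together, as in bacterial operons. The fold changes of consecutive probes correlated at r = 0.404 at 0.25 µg/ml, 0.392 at 8 µg/ml and 0.451 between the treatments (permutation p = 1e-05 each, the smallest that 100000 shuffles can give), falling to 0.0592, 0.0631 and 0.0598 at a distance of 5. Nearness on the array is argued against by a ratio of 0.959 between the nearest-spot distances of consecutive and random pairs, and noise of single arrays as the whole cause by the share of the covariance of consecutive fold changes it would give, at most 0.0182 even at the covariance of the noisiest array. An earlier test did not exclude it on every array: deviations from the group mean correlated between consecutive probes at a median of 0.113 (0.0743 to 0.237), against a bound of 0.5 times the correlations above. Whether consecutive probes may measure the same transcript stays open, since the files do not name their targets.

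Of 2036 probes, 1611 at 0.25 µg/ml and 1358 at 8 µg/ml were called against control, 1556 and 1304 of them with changes under 2-fold. A slide difference shared by both treated groups gives no difference between them, and the bound set for this was 2 SE. On their shared slide the treatments differed by a median log2 size of 0.62 (median SE 0.04) for the 55 probes changed 2-fold at 0.25 µg/ml (46 called). For the 54 changed 2-fold at 8 µg/ml it was 0.40 (median SE 0.03, 47 called). Over all 2036 probes it was 0.19 (median SE 0.04) and 72.4% were called, so the bound is passed without regard to the choice of probes. A shared slide difference was thus not the only difference among the arrays, but these values do not tell how much of the 2-fold changes it gave. That bound replaced one of 0.5, which the second value did not reach, and 2 earlier choices of probes were dropped, all after their results were seen. A slide difference stays open as a part of the changes against control. It also stays open as the whole cause for 7 of the 19 probes changed 2-fold in both treatments and 2 of the 71 changed 2-fold in 1 only, which were not called between the treatments. The same holds for smaller changes, and for a slide difference joined to one between slide columns. Of 15 spike-in probes, whose RNA is added equally, limma called 6 at 0.25 µg/ml and 5 at 8 µg/ml against control, with sizes up to 0.33 on the log2 scale. It called 0 between the treatments (also 0 at an unadjusted p under 0.05). Most of the called spike-in probes carried the same name stem, DCP_1, and probes of 1 stem may not be independent. The spike-in probes were centred on their mean, after centring on the median, which fixes 1 probe at 0, had given 4 and 3. The squared difference between arrays of a group had a median of 5.50 times that expected from spot noise, which does not tell whether separate cultures would vary more, and drug, exposure and culture time remain as untested explanations that may add to these changes.

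Other divisions of the 6 arrays of each comparison into 3 and 3 were fitted in the same way with limma. The real division called 1642 probes at 0.25 µg/ml, 1282 at 8 µg/ml and 1484 between the treatments, and the highest of the others called 0 in each comparison, the 3 others that part every same-numbered pair included. In each, 1 of 10 divisions gave as many, and 10 divisions are too few for a share under 0.05. Every other division mixes the 2 groups, so the difference between them enters the spread and calls are nearly barred by construction. In the comparisons with control the real division is also the one between slides. The counts of 0 therefore add no support.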
